A study of Homo sapiens with 28 samples.

How the data were processed

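Genomic DNA of MCF-7 cells kept for 24 h at 0.5% or 21% oxygen was immunoprecipitated with an antibody against 5mC (mDIP, 16 libraries) or 5hmC (hmDIP, 6 libraries) and sequenced, and 6 input libraries were sequenced without immunoprecipitation. Groups, experiment numbers and replicate letters were taken from the sample titles. For mDIP, each of 4 experiments held 2 replicates per oxygen level, A and B. The titles do not say whether A and B were separate cultures, and the fits count them as separate libraries. For hmDIP and input each of 3 experiments held 1 library per oxygen level.

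The authors deposited raw read counts per promoter for mDIP, in a table of 20271 Ensembl gene identifiers, and raw read counts per region for hmDIP and input, in a table of 290382 regions with chromosome, start and end, per the file headers. Bowtie 0.12.8, Bismark and edgeR 3.6.8 and the build GRCh37 (hg19) are named in the submitters' processing notes, with no role or order. How regions were called, reads filtered and promoters bounded is not given in the sources used here. The largest region end on chromosome 1 was 249240750, and positions are given as in the deposited table. The authors also deposited log2 fold changes and p-values of their own comparisons, per the file headers, which are quoted only where the authors' deposited table is named. The numbered mDIP comparisons of that table were matched to experiments by the correlation of its fold changes with those of every experiment and pair of experiments, which was -0.997 or stronger for each, so its sign was found to be normoxia minus hypoxia. That mDIP table listed only promoters under a p limit, with a largest p of 0.0100.

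A further promoter table with 16 columns of hmDIP counts was not used, because its column names match no sample, and neither was the authors' table of comparisons made from it. The Ensembl identifiers of the promoters were not paired with gene names: 0 of 20271 matched the table of gene names at hand. The 17 gene lists fixed before the data were examined, the comparison of hmDIP at promoters and the joint comparison of 5mC and 5hmC at the same promoters were therefore not run. No genome of the build was used, so the planned correction for GC content was not run and regions are described by position alone.

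Counts were tested with edgeR 4.0.16 (quasi-likelihood F test with a trended dispersion, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) after TMM scaling and edgeR's filter on low counts (minimum count 10, minimum total 15) in R 4.3.3. Experiment was a block in each fit, because the series describes independent experiments with both oxygen levels side by side. The deviations of libraries from their oxygen group's mean correlated between oxygen levels with r from 0.388 to 0.756 within mDIP experiments, and from 0.0583 to 0.218 within the 3 hmDIP experiments, across features. For input r ran from -0.0148 to 0.00841. Between experiments it ran from -0.503 to 0.589 in mDIP and from -0.210 to 0.0458 in hmDIP. The highest mDIP values were those between experiments 2 and 4, from 0.306 to 0.589. The input contrast of hmDIP was an antibody by oxygen interaction over 12 libraries, and enrichment over input was tested with library-size scaling. Standard errors of log2 fold changes were derived from the F statistic. Values in CPM were scaled by TMM, and log2 CPM used a prior count of 2.

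Promoters or regions were named by a rule fixed before the data were examined: the 8 higher and 8 lower with the largest fold change among those past the threshold with 1 sign in all experiments and a mean of at least 1 CPM over the libraries, and the 4 higher and 4 lower with the smallest p. Where fewer than 5 passed, those with the smallest p were to be named with the statement that they did not pass, and this was limited to 2 higher and 2 lower promoters because their names were not paired. The parts of the rule that name genes did not apply.

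Expected numbers of losses per chromosome, width class or window were summed over 50 strata of mean log2 CPM (10 within classes of enrichment over input, and 10 crossed with 10 of hmDIP over input where both were matched), with an exact Poisson 95% interval of the observed number, and tested with the Cochran-Mantel-Haenszel test over the strata. Windows of 5 Mb with at least 100 regions were compared, 574 in all, of which 5 passed a Benjamini-Hochberg adjusted Poisson p of 0.05. Promoter level classes were 10 equal groups by mean log2 CPM.

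The fits were tested on simulated negative binomial counts with 200 changed features. Means were those of each experiment with both oxygen levels pooled, library sizes were the real ones, and dispersions followed the fitted trend. Each change was the same in every experiment. In the mDIP simulation 201 promoters were called, of which 17 were false, and in the hmDIP simulation 69 regions were called, of which 1 was false. For hmDIP 4.48% of the regions changed by 1.5 times, 34.3% of those changed by 2 times and 63.6% of those changed by 3 times were recovered. Counting intervals cover counting error only. Pairs of libraries of the same group differed by more than sampling noise in mDIP and hmDIP, with a chi-square per degree of freedom of 1.07 to 12.7 and of 1.09 to 1.52. Input pairs, with few reads per region, ranged from 0.997 to 1.02, and every pair of input libraries was alike in this respect, so they were kept as separate libraries.

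The alternatives were a fit without the block, library-size and RLE scaling, no count filter, a mean of at least 20 counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), a tested fold change of at least 1.2, and each library or experiment left out. For mDIP, replicates A and B were also summed within each experiment and oxygen level. Alternatives chosen after seeing the data were smooth offsets on level or on read density (lowess span 0.3), scaling to the least enriched regions (the 322 regions with the lowest 2% of hmDIP over input among those with at least 50 input reads), scaling shifted to the authors' table, edgeR's likelihood ratio test, and all those run within single mDIP experiments, for the oxygen by experiment interaction, for the median fold change of the highest level class in experiment 4 and for the ratios of losses on chromosome 16, in regions over 5000 bp and near chromosome ends.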

Results

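MCF-7 is an established line of luminal, oestrogen-receptor-positive breast cancer cells. It was kept for 24 h at 0.5% oxygen (hypoxia) or 21% oxygen (normoxia), and its genomic DNA was sequenced after immunoprecipitation. Methylated DNA immunoprecipitation (mDIP) used an antibody against 5-methylcytosine (5mC), and hydroxymethylated DNA immunoprecipitation (hmDIP) used an antibody against 5-hydroxymethylcytosine (5hmC), the product of 5mC oxidation by the oxygen-dependent TET enzymes. The mDIP set held 16 libraries, 8 per oxygen level, from 4 experiments with replicates A and B per oxygen level in each. Whether A and B were separate cultures is not stated in the labels, and n = 8 below counts both. The hmDIP set held 6 libraries, 3 per oxygen level, from 3 experiments, and 6 libraries of input DNA that had not been immunoprecipitated were matched to them. Counts over 20271 promoters summed to between 707280 and 1576295 per mDIP library. Counts over 290382 genomic regions summed to between 6339557 and 11347440 per hmDIP library and between 885971 and 1538497 per input library.

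The first comparison asked whether promoters carried more or less 5mC in hypoxia over all 4 experiments. No promoter passed the threshold in either direction. The lowest p values among promoters with more signal in hypoxia belonged to ENSG00000198062, at 39.7 ± 28.2 CPM (counts scaled to library size) in hypoxia and 26.8 ± 17.2 in normoxia (SD, n = 8 each), and to ENSG00000183434, at 139.7 ± 17.0 CPM against 106 ± 31.8. Their log2 fold changes were 0.55 ± 0.13 (SE) and 0.45 ± 0.10, above 0 in 4 of 4 and 3 of 4 experiments. Among promoters with less signal, ENSG00000266076 stood at 20.1 ± 7.34 CPM in hypoxia and 31.3 ± 12.4 in normoxia, and ENSG00000125571 at 7.22 ± 4.52 against 14.9 ± 6.15, with no read in 1 hypoxia library. Their log2 fold changes were -0.60 ± 0.14 and -0.94 ± 0.22, below 0 in 4 of 4 experiments each. None of these 4 promoters passed, with an adjusted p of 0.264 for each from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

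Of 18503 promoters tested with experiment as a block, edgeR called 0. At an unadjusted p under 0.05 there were 1619, of which 910 were higher and 709 lower in hypoxia. DESeq2 and limma-voom also called 0, as did the fit on replicates A and B summed. At the same depth and fitted dispersion, simulated libraries recovered 80.6% of promoters changed by 1.5 times and 98.5% of those changed by 2 times. Each simulated change was the same in every experiment, so recovery of changes that differ between experiments was not tested. Simulated replicates A and B were drawn as independent libraries, so these shares may be too high if A and B were not separate cultures. With A and B summed in the real data, the edgeR adjusted p of the 4 named promoters was 0.909. In the real data ENSG00000125571, 1.92 times lower in hypoxia, did not pass. The count rested on experiment 1, since leaving it out gave 97 promoters, 91 higher and 6 lower, with all 4 named promoters among those that passed.

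The second comparison asked whether the oxygen response of 5mC was the same in the 4 experiments. Experiment 4 held 1253 promoters with more 5mC in hypoxia and 263 with less. Experiment 3 held 92 with more and 12 with less, and experiments 1 and 2 held 0. Each test within an experiment rested only on the spread between replicates A and B. The gains in experiment 4 lay at promoters that carried the strongest mDIP signal. With promoters ordered by mean level into 10 classes, 852 of the 1851 in the highest class (46.0%) gained and 4 lost, whereas in the lowest class 0 gained and 52 lost. The median log2 fold change of experiment 4 rose from -0.34 in the lowest class to 0.47 in the highest (0.30 with library-size scaling), and from -0.35 to 0.49 when the classes were set from experiments 1 to 3 alone. In the highest class it was -0.05 in experiment 1, 0.08 in experiment 2 and 0.09 in experiment 3.

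**Figure D1:**
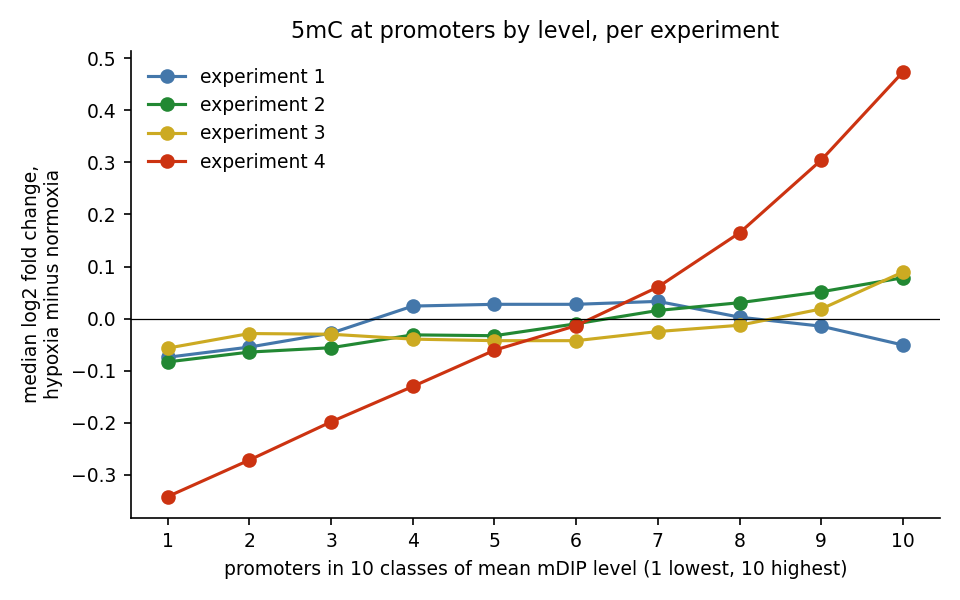
Median log2 fold change of promoter mDIP counts (hypoxia minus normoxia, vertical axis) in 10 classes of mean mDIP level (horizontal axis), with 1 line per experiment. Experiment 4 runs from -0.34 in the lowest class to 0.47 in the highest, while the other 3 experiments stay between -0.08 and 0.09.

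The promoters of the highest class took 34.9% ± 0.0931 of all promoter counts in hypoxia and 28.7% ± 1.40 in normoxia in experiment 4 (SD, n = 2 each). In experiment 3 they took 43.1% ± 1.05 and 41.4% ± 0.545, in experiment 2 35.0% ± 1.29 and 33.8% ± 0.812, and in experiment 1 46.4% ± 0.53 and 47.2% ± 3.52. Over all 16 libraries the share was 39.9% ± 5.45 in hypoxia and 37.8% ± 7.70 in normoxia (SD, n = 8 each). That difference was smaller than the spread between experiments, with a two-sided exact permutation p of 0.0818 over the 1296 relabellings within experiments and 0.537 over all 12870 relabellings.

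Of the 1253 promoters that gained in experiment 4, 902 (72.0%) lay above 0 in experiment 3 and 919 (73.3%) in experiment 2. In experiment 1, 333 (26.6%) did so. There the share was 72.3% without normoxia replicate 1A. It was 37.0% and 21.5% without hypoxia replicates 1A and 1B, and 12.7% without normoxia replicate 1B. With single libraries left out, experiment 2 gave 52.0% to 82.0%, lowest without hypoxia replicate 2B, and experiment 3 gave 61.6% to 76.4%. Among all promoters, with every library, the shares above 0 were 48.9%, 50.5% and 48.6% in experiments 3, 2 and 1. These are not matched on level. In the highest class, which held 852 of the 1253, the median log2 fold change was 0.09, 0.08 and -0.05 in these experiments. Of the 92 gains of experiment 3, 52 were also gains of experiment 4, where independent lists would share 6.86 and lists drawn at random within the level classes 27.2. The exact Fisher p of this overlap was 7.19e-37, and the Cochran-Mantel-Haenszel p within level classes, not an exact test, was 2.70e-10, both across promoters, which are not independent replicates. Across promoters, fold changes of experiments 2 and 4 correlated with r = 0.18, and the other 5 pairs of experiments ranged from -0.01 to 0.06. Libraries of experiments 2 and 4 were also alike in their deviations from the mean of their oxygen group, with r from 0.306 to 0.589 between oxygen levels. Whether experiments 2 and 4 shared a batch is not stated in the labels, so experiment 2 may not be an independent check on experiment 4.

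The interaction of oxygen with experiment passed for 379 of 18975 promoters, for 86 with library-size scaling, 129 with RLE scaling and 40 with the smooth trend on level removed, for 1 when experiment 4 was left out and for 23 when experiment 3 was left out. In experiments 1 and 2, 432 and 838 promoters had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 in each. Scaling by library size, which moved the median log2 fold change of experiment 4 to -0.16, gave 681 gains and 571 losses there, and removing the smooth trend of fold change on level gave 164 gains and 135 losses. DESeq2 called 483 promoters in experiment 4 and 16 in experiment 3. Without hypoxia replicate 4A, hypoxia replicate 4B or normoxia replicate 4B, experiment 4 had 777, 727 and 890 calls. Experiment 3 had 0 without normoxia replicate 3A and 36 to 52 without any other of its libraries, and experiment 1 had 70 without normoxia replicate 1B. In the authors' deposited table, whose numbered comparisons were matched to experiments by their fold changes, 1756 of 2339 listed promoters were higher in hypoxia in experiment 4, 478 of 683 in experiment 3, 118 of 234 in experiment 2 and 81 of 146 in experiment 1.

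The third comparison asked where 5hmC rose or fell in hypoxia. Losses prevailed: 1179 regions had less 5hmC signal in hypoxia and 58 had more. The regions called lower fell by a median of 1.75 times, with log2 fold changes from -2.22 to -0.29 around a median of -0.80, and they had a median width of 1650 bp. The regions called higher rose by a median of 1.93 times, with log2 fold changes from 0.49 to 1.94, and had a median width of 900 bp. All 58 regions called higher and 1158 of the 1179 called lower moved in the same direction in all 3 experiments, which calling on the same experiments favours. With experiment 1 left out of the calls, 596 of 650 losses lay below 0 in it and 24 of 42 gains above 0. With experiment 2 left out, 754 of 879 losses and 30 of 60 gains did so, and with experiment 3 left out 16 of 16 losses and 1 of 2 gains. In the left-out experiment 1, 2 or 3 these losses had a median log2 fold change of -0.34, -0.36 or -0.78. Calling on the same experiments also favours large fold changes, so the median fall of 1.75 times is likely too large.

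The 4 losses with the smallest p were 1950 to 9450 bp wide. On chromosome 20, positions 55199101 to 55203600 (GRCh37, 4500 bp), the count fell from 25.4 ± 3.75 CPM in normoxia to 15.3 ± 2.46 in hypoxia (SD, n = 3 each), a log2 fold change of -0.73 ± 0.11 (SE, edgeR adjusted p = 4.79e-05). On chromosome 19, positions 50357851 to 50367300 (9450 bp), it fell from 55.9 ± 8.25 to 37.9 ± 3.75 CPM, a log2 fold change of -0.57 ± 0.09 (edgeR adjusted p = 7.80e-05). On chromosome 16, positions 3066901 to 3068850 went from 11.7 ± 1.99 to 6.10 ± 0.339 CPM and positions 89760751 to 89765100 from 22.1 ± 4.26 to 13.4 ± 2.89 CPM, with log2 fold changes of -0.96 ± 0.15 and -0.72 ± 0.11. The 4 gains with the smallest p were on chromosome 8 at 134222551 to 134225550 (0.61 ± 0.12, from 10.6 ± 1.34 to 16.2 ± 2.03 CPM), on chromosome 17 at 37780201 to 37781850 (0.72 ± 0.15), and on chromosome 5 at 56835901 to 56836500 (1.43 ± 0.31) and 64219351 to 64220100 (0.91 ± 0.20). Their edgeR adjusted p ran from 0.00327 to 0.00842, and each was higher in 3 of 3 experiments.

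**Figure D2:**
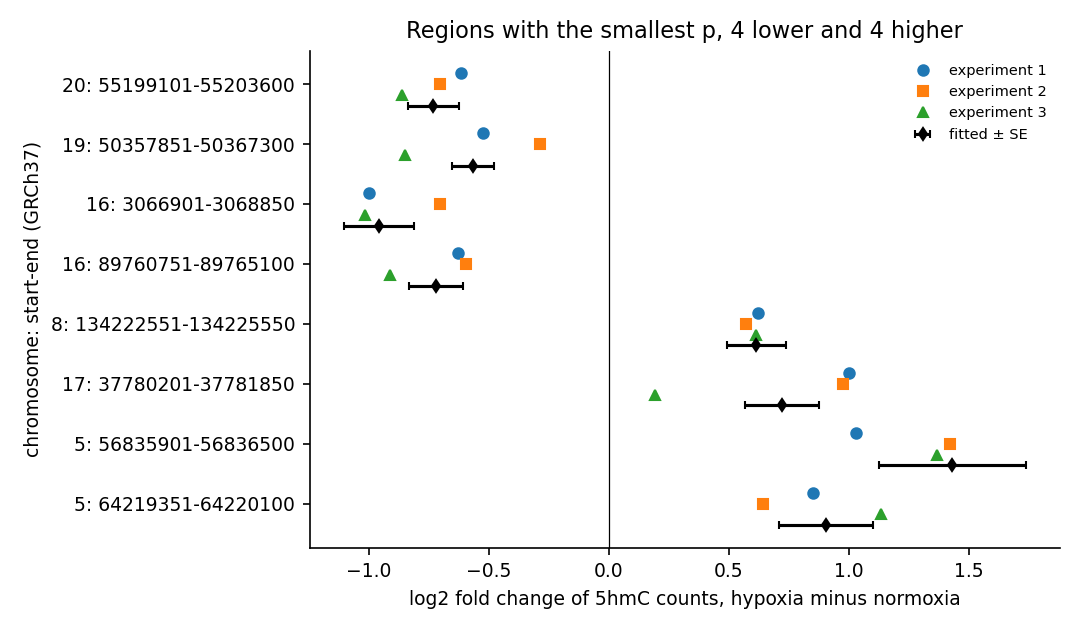
Log2 fold change of hmDIP counts (hypoxia minus normoxia, horizontal axis) of the 4 losses and 4 gains with the smallest p, by position. Coloured points are the 3 experiments and diamonds the fitted value ± SE, which runs from -0.96 to 1.43, with the 3 experiments of each region on the same side of 0.

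Among called regions with 1 sign in all experiments and a mean of at least 1 CPM, the largest fold changes were at narrow regions with few reads. The 8 largest losses there were 450 to 900 bp wide and held between 59 and 114 hmDIP reads over the 6 libraries. They were led by chromosome 12 at 3854101 to 3854550, from 1.65 ± 0.521 to 0.412 ± 0.162 CPM (log2 fold change -2.01 ± 0.45), chromosome 15 at 68487151 to 68487600 (-1.82 ± 0.42), chromosome 18 at 12364951 to 12365400 (-1.79 ± 0.43) and chromosome 13 at 109569001 to 109569600 (-1.73 ± 0.41). The other 4 lay on chromosome 1 at 39715051 to 39715950, 154929451 to 154930050 and 183129301 to 183130200, and on chromosome 9 at 99135001 to 99135600, with log2 fold changes from -1.71 to -1.65. The largest gains were on the X chromosome at 28364851 to 28365300, from 0.416 ± 0.280 to 1.63 ± 1.07 CPM (1.94 ± 0.47), chromosome 14 at 34867951 to 34868550 (1.72 ± 0.40), chromosome 2 at 62923051 to 62923800 (1.53 ± 0.33) and chromosome 8 at 39070951 to 39071550 (1.51 ± 0.39). They were followed by chromosome 2 at 88975651 to 88976250, chromosome 18 at 36998101 to 36998850 and chromosome 6 at 33373201 to 33373800, with log2 fold changes of 1.42, 1.30 and 1.29. The 8 largest gains, among which was the chromosome 5 region at 56835901 named above, held between 50 and 101 hmDIP reads. These 16 regions held between 6 and 26 input reads each over the 6 input libraries, too few for the input comparison.

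The losses were unevenly spread over the genome, in descriptions chosen after the calls were seen. Regions wider than 5000 bp held 90 losses among 559 regions, where regions of like read depth would give 17.7, a ratio of 5.08 (exact Poisson 95% interval 4.08 to 6.24). Regions over 2000 and up to 5000 bp held 351 against 194 expected, and those over 450 and up to 750 bp held 116 against 236. Chromosome 16 held 159 losses against 66.4 expected, a ratio of 2.39 (2.04 to 2.80), and of 2.00 (1.70 to 2.33) when region width was matched too. Chromosome 17 held 72 against 49.1, but with width matched its ratio was 1.21 with an interval of 0.951 to 1.53. Chromosome 1 held 61 against 98.5, with an adjusted p of 0.00104 from the Cochran-Mantel-Haenszel test over 23 chromosomes, beside 1.12e-30 for chromosome 16 and 0.00746 for chromosome 17. Within chromosome 16 the losses lay toward the ends, with 47 against 9.83 expected in the first 5 Mb and 41 against 12.5 between 85 and 90 Mb. Without either library of experiment 3, 23 losses were left, too few to show such a spread: 0 were wider than 5000 bp, and chromosome 16 had a ratio of 2.42 with a Cochran-Mantel-Haenszel p of 0.243. Regions are not independent replicates, and these tests describe the spread of calls over the genome.

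**Figure D3:**
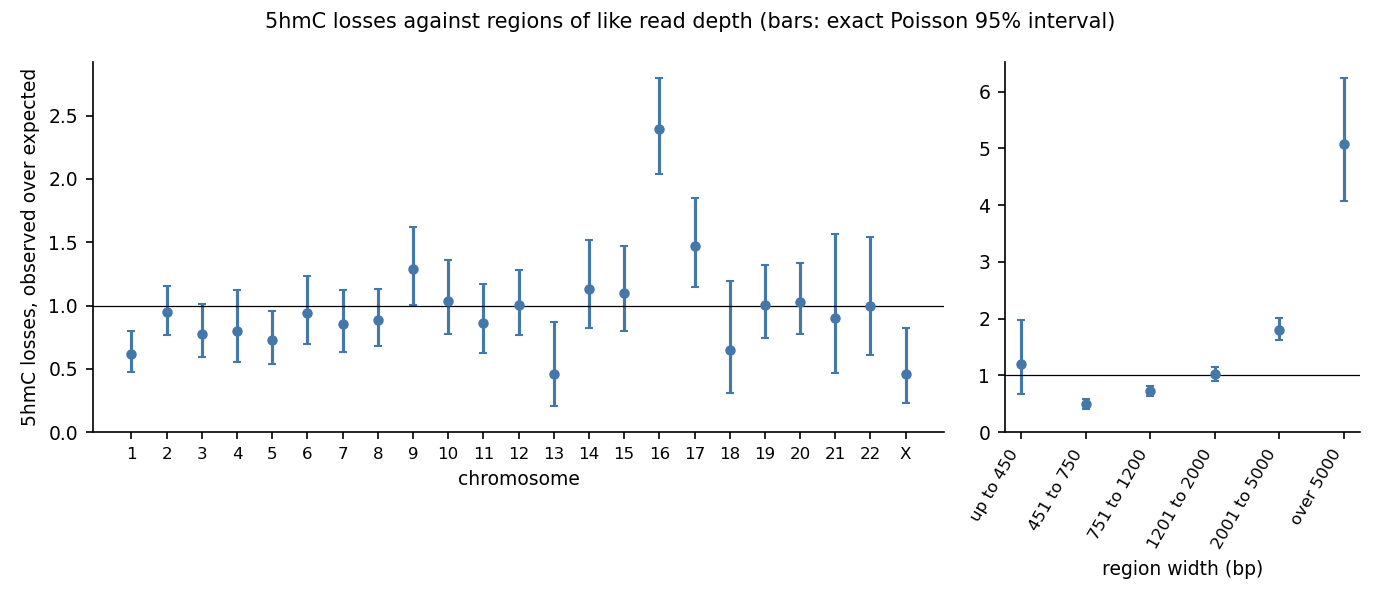
Regions with less 5hmC in hypoxia, observed over the number expected from regions of like read depth (vertical axis), by chromosome and by region width, with exact Poisson 95% intervals. Chromosome 16 stands at 2.39 and regions over 5000 bp, for which depth was not fully matched, at 5.08.

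**Figure D4:**
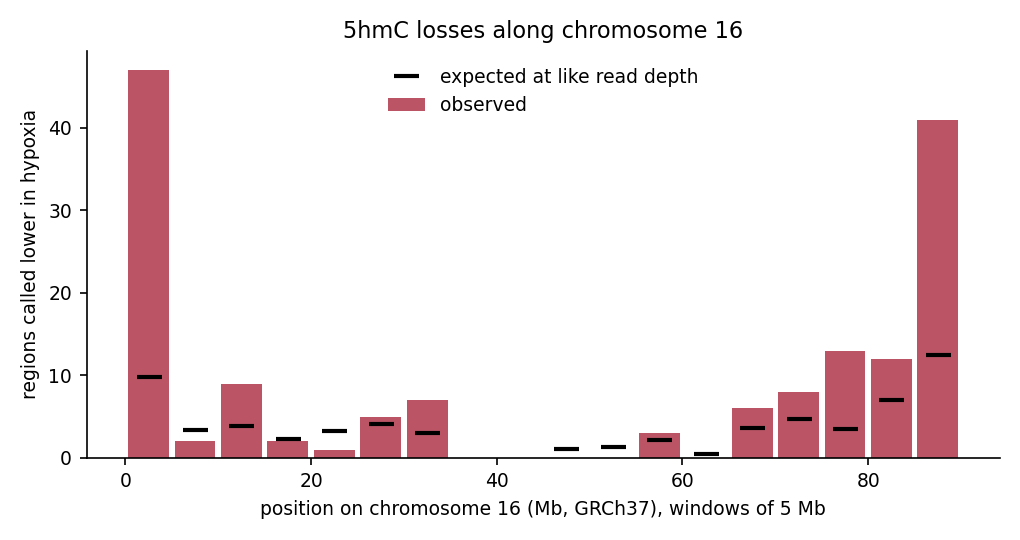
Regions with less 5hmC in hypoxia along chromosome 16 in windows of 5 Mb (bars) and the number expected from regions of like read depth (dashes), for windows with at least 100 regions. The first window holds 47 and the window from 85 to 90 Mb holds 41.

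Of 277427 regions tested with experiment as a block, 1237 passed edgeR's quasi-likelihood test, and 28527 had an unadjusted p under 0.05. The calls depended on the model and on experiment 3: without the block, and with DESeq2, 0 regions passed, with 17483 and 2161 at an unadjusted p under 0.05, 25 passed when either library of experiment 3 was left out, and 599 and 718 passed without the normoxia and the hypoxia library of experiment 1. The excess of losses depended on the scaling, with 111 losses and 81 gains when libraries were scaled to the least enriched regions. At an unadjusted p under 0.05 from edgeR, that scaling gave 28131 higher and 9074 lower, against 10199 and 18328 in the main fit. It moved the median log2 fold change of all regions from 0.01 to 0.13. In the authors' deposited table, 10001 regions were lower and 18 higher at a false discovery rate under 0.05. Its fold changes lay a median of -0.21 below those computed here (log2), nearly evenly over regions, and 1178 of the 1179 losses and 17 of the 58 gains were among its calls in the same direction.

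The input libraries served as the background of the hmDIP comparison. Of 16190 regions with enough input reads, edgeR called 0 between hypoxia and normoxia, with 711 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Of the 4 losses with the smallest p, that on chromosome 20 had an input log2 fold change of -0.05, that on chromosome 19 of 0.19 and that on chromosome 16 at 89760751 of -0.20, and the other held too few input reads. On simulated input libraries, 28.4% of regions changed by 2 times and 59.1% of those changed by 3 times were recovered.

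The change of 5hmC beyond the change of input was tested in 231707 regions. No region passed. The 4 losses with the smallest p stood at -0.71 ± 0.27 (log2, SE) on chromosome 20, -0.79 ± 0.27 on chromosome 19, and -1.08 ± 0.50 and -0.55 ± 0.31 on chromosome 16 at 3066901 and 89760751, with edgeR adjusted p from 0.811 to 0.966. At an unadjusted p under 0.05 there were 12097 regions, 5335 higher and 6762 lower. DESeq2 called 0 and limma-voom 21, of which 20 were lower. On simulated libraries 0% of regions changed by 2 times and 3.03% of those changed by 3 times were recovered, so changes of this size were not detectable in this contrast at the depth of the input.

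The last comparison asked which regions held hmDIP signal above input, averaged over oxygen levels. With library-size scaling, 27611 regions stood above input and 24290 below it among 202946 tested, relative to the average region (edgeR adjusted p under 0.05). TMM scaling gave 33479 above and 14784 below. Of the losses in hypoxia, 148 lay in regions above input, where like read depth would give 339, and 216 lay in regions below it, where it would give 115. Most, 762 against 647 expected, lay in regions that passed in neither direction, and 53 against 78.0 in regions not tested.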

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

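The tests of level trend and of other experiments in this part, the other settings of the interaction, and the count of relabellings by the oxygen split of experiment 4, were chosen after the result was seen, and the test of depth before. The 5mC response to oxygen differed between the 4 experiments at 379 promoters by the interaction test, which is what brought this result up, but at 86 with library-size scaling, 129 with RLE scaling and 40 with trend offsets. Relabelling the oxygen levels within experiments gave as many in 17 of 100 relabellings, the real one included, and up to 1614 in another, so chance is not excluded for this number. Of the other relabellings, 34 kept or mirrored the oxygen split of experiment 4, with a median of 365 promoters, and 16 of them gave at least 379, while the 65 that broke it gave at most 1. The high counts thus followed the split of the experiment 4 libraries by oxygen level. No library stood apart from the 8 of its group in total count, in the share of the highest level class or at the 4 named promoters, but each group pools 4 experiments, which widens its range. Within experiments, normoxia replicates 1A and 1B differed most, with a chi-square per degree of freedom of 1.92 against 1.07 to 1.43 in the other 7 pairs.

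The number fell to 1 without experiment 4, which held an excess of 5mC gains at promoters with strong signal. Depth is argued against: thinning its 4 libraries to 724468 reads left 1062 calls, 70.1% as many, with 85.0% gains. A gain shared by all experiments stays open, since the share of these promoters above 0 in experiment 1 turned on a single library. It was 26.6% with all libraries, 72.3% without normoxia replicate 1A, and 12.7% to 37.0% without any other library of experiment 1. A difference in immunoprecipitation enrichment between its hypoxia and normoxia libraries and a true gain in proportion to the 5mC level cannot be told apart, and both stay open. Removing the trend on level took gains from 82.7% to 54.8% of the calls, but that step centres fold changes at every level and so bears on neither.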

How the results depend on the processing

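Planned settings were fixed before the data were examined, and those on smooth offsets, least enriched regions, the authors' level, the likelihood ratio test, single mDIP experiments, the interaction, and the ratios of losses by region class were chosen afterwards. The cause of each change below was not tested unless stated. For 5hmC regions, against 1237 calls, the fit with no replicate block gave 0, DESeq2 0, a tested fold change of at least 1.2 gave 26, offsets on read density 2003, scaling to the least enriched regions 192 and the authors' level 16057, while leaving out single libraries gave 25 to 855, lowest without either library of experiment 3. The likelihood ratio test, trend offsets, RLE and library-size scaling, limma-voom and both count filters stayed within 1.5 times. Gains made up 4.69% of calls, 0% at a tested fold change of at least 1.2, 42.2% when scaled to the least enriched regions, 0.274% at the authors' level and 4.18% to 8.00% with single libraries left out. All 23 named regions kept their direction under every setting that gave a value. They were chosen on these same data and had the same sign in every experiment, so this was largely set by the choice. Of them, 23 lost their call with DESeq2, 21 of the 21 tested without the block, 20 without either library of experiment 3, 19 at a tested fold change of at least 1.2, 14 and 15 without the normoxia and the hypoxia library of experiment 1, 9 without either library of experiment 2, 9 with limma-voom and 8 when scaled to the least enriched regions. Losses in regions over 5000 bp were 3.04 to 6.02 times those expected, but 0 without hmDIP replicate 3 of either oxygen level and 0 at a tested fold change of at least 1.2. Those near chromosome ends were 1.23 to 2.45 times, but 0.943 and 0.942 without replicate 3 of normoxia and hypoxia, where 23 losses remained, and at 1.2 the Cochran-Mantel-Haenszel p over regions, not an exact test, was 0.878. Those on chromosome 16 were 1.66 to 3.09 times, but that p, not exact, was 0.243 without replicate 3 of either oxygen level and 0.255 at 1.2.

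For hmDIP beyond input, against 0, a mean of at least 20 counts gave 5 and limma-voom 21, and single libraries left out gave 0 to 4. Input stayed at 0 throughout. Enrichment over input gave 48263 regions with TMM against 51901. For mDIP promoters, against 0, trend offsets gave 1 and leaving out an experiment 0 to 97, highest without experiment 1, and no other setting, the fit with no replicate block among them, gave any. The interaction, 379 promoters, gave 86 with library-size scaling, 129 with RLE, 40 with trend offsets and 1 to 532 with an experiment left out, lowest without experiment 4 (1) and 23 without experiment 3. Experiment 4, with 1516 calls, gave 483 with DESeq2, 299 with trend offsets and 727 to 1519 with a library left out. The median log2 fold change of its highest level class, 0.47, was 0.30 with library-size scaling and 0.51 with RLE. Experiment 3, with 104, gave 16, 41 and 0 to 52, and experiment 1, with 0, gave 0 to 70. The GC correction and the alternatives for promoters in hmDIP, for the joint comparison and for the gene lists were not run. At 885971 to 1538497 reads per input library, 16190 of 290382 regions could be tested in input.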

Other observations

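The tests of scaling and of regions matched on hmDIP over input, the count of splits by experiment 4, and the descriptions of chromosome ends, chromosome 16, wide regions and input read density were chosen after the result was seen. Losses of 5hmC also lay near the ends of chromosomes other than 16. The first and last 5 Mb covered on each chromosome held 295 losses against 172 expected from read depth, a ratio of 1.71 (exact Poisson 95% interval 1.52 to 1.92), and 205 against 135 when chromosome 16 was left out. The ratio was 0.943 and 0.942 without the normoxia and the hypoxia library of experiment 3, where 23 losses were left in each case, and 1.23 at a tested fold change of at least 1.2, with no excess past the test in any of these. Over all 32793 regions near ends the median log2 fold change was -0.04, -0.05 and -0.11 in experiments 1, 2 and 3, against -0.01, 0.01 and 0.01 elsewhere. Over the 559 regions wider than 5000 bp it was -0.15, -0.10 and -0.23. Among these, the 87 with over 100 input reads per kb held 9 losses against 2.76 expected, a ratio of 3.26 (1.49 to 6.19), and the other 472 held 81 against 15.0, a ratio of 5.41 (4.30 to 6.72). Depth was not fully matched for regions this wide. On chromosome 16 the share of hmDIP reads was 5.17% ± 0.166 in hypoxia and 5.39% ± 0.163 in normoxia (SD, n = 3 each), lower in hypoxia in 3 of 3 experiments, whereas the share of input reads was 5.13% ± 0.0207 and 5.02% ± 0.123. The smallest p that an exact permutation test of 3 against 3 libraries can give is 0.1.

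The excess of 5hmC losses over gains did not come from experiment 3 alone: of 650 regions called lower in experiments 2 and 3, 596 (91.7%, exact 95% interval 89.3 to 93.7) lay below 0 in experiment 1, and of 879 called in experiments 1 and 3, 754 (85.8%) did so in experiment 2. That was at least 36.6 percentage points more often than among all regions, with medians of -0.34 and -0.36 (log2) in the left-out experiment. Of the regions called higher, only 24 of 42 and 30 of 60 kept their sign there. Scaling stays open as a source of the excess, since gains were 4.69% of calls with TMM, 42.2% when scaled to the least enriched regions and 0.274% at the authors' level. All 9 other splits of the 6 hmDIP libraries gave 0 calls against 1237, but 10 splits are too few for a share under 0.05.

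The losses in regions over 5000 bp exceeded those expected from the depth strata, of which the highest has no upper limit. A change of the DNA itself is argued against. In the 90 such regions called lower, the input share in hypoxia was at least 1.00 times that in normoxia in each experiment. Over all 559 the input share was 1.01, 1.02 and 1.01 times and the hmDIP share 0.924, 0.977 and 0.922 times. In the 472 with fewer input reads the hmDIP share was 0.929, 1.01 and 0.922 times. With the trend on read density removed, 174 of the 559 were called lower, a ratio of 4.84 (4.15 to 5.61). The losses in these regions thus did not vanish with that trend. The ratio rests on the same open highest stratum of depth, so it does not decide whether the trend adds to the concentration. Background reads in regions with little hmDIP over input stay open as a source of this concentration. The ratio was 7.81 (6.28 to 9.60) among regions matched on depth and on hmDIP over input and 6.84 in regions above input alone. Both used fewer strata of depth than the main ratio of 5.08, and in the former the expected losses fell from 17.7 to 11.5. A coarser match on depth can itself raise such ratios, so they do not decide this. Losses in general were in excess below input (216 against 115) and fewer than expected above it (148 against 339). Most lay in regions that passed in neither direction (762 against 647). Base composition was not tested, since no genome of the build was used here, and may account for part of the pattern at wide regions and chromosome ends. Loss of 5hmC under low oxygen, which the design names, stays open as a hypothesis.

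The 10 splits of the input libraries, and those of the hmDIP libraries beyond input, are too few for a share under 0.05, with a highest other of 0 in each, and with 0 calls in the real split they say nothing, since all 10 of 10 give as many. The same holds for mDIP promoters over all experiments, where the real split gave 0 calls and 100 of 100 splits gave as many, so nothing is excluded by them. The highest of these gave 560, and the highest of 100 splits within experiments gave 326, in a split that kept or mirrored the oxygen split of experiment 4, while the 65 that broke it gave at most 1. For enrichment over input the real split gave 51901 regions, 1 of 40 splits (the real one) gave as many, and the highest other gave 2485. The real split parts immunoprecipitated from input libraries and the others mix them, so no conclusion is drawn from this count.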
